A study of Mus musculus with 12 samples.

How the data were processed

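RNA was measured in 12 samples of mouse tongue epithelium, 6 from mice given diphtheria toxin (DT) and 6 from mice given phosphate-buffered saline (PBS). The mice carried Langerin-DTR, in which the human receptor for the toxin is made by cells that express langerin (Cd207), so that the toxin kills those cells. Per the labels, injections were given 2 times per week from 2 weeks of age until the mice were adult. Per the labels' protocols, the epithelium was lifted off the tongue after dispase, digested with collagenase and DNase, and sequenced with a stranded mRNA kit. Groups and replicate numbers were taken from the sample titles. All 12 samples had high counts of Y-linked genes (1110 to 2060 for Ddx3y) and 0 to 8 counts of Xist, so all carried the pattern of male mice.

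The authors deposited 1 table with a raw count and a normalized value per gene and sample. Per the submitters' processing notes, the tools were cutadapt 2.10, TopHat2 2.1.1, HTSeq 2.01 and DESeq2 1.36.0, and the genome build was GRCm39; the annotation and the strand setting of the counting were not given in the sources used here. The deposited counts were whole reads per gene, not normalized. The deposited normalized values were a signal equal to the count divided by a size factor per sample. Size factors recomputed with DESeq2's median of ratios differed from those in the table by 0%. Normalized values were listed for 20540 genes, those with a total count of at least 10; they were used only for this check, and 0 columns belonged to no sample. Of 55414 genes in the table, 6250 had blank counts and were left out, 49164 had counts and 30102 had at least 1 count. Several immune receptor genes, among them Trac and Trdc, were among the blank entries.

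The reference annotation at hand was of build GRCm38, not that of the counts. No coordinates are therefore given, and this annotation served only for gene names and for which genes neighbour each other; 94.0% of the tested genes matched it. Genes with near-identical copies are uncertain, because reads shared by copies can be split or lost in counting. This holds for Hba-a1 and Hba-a2, Hbb-bs and Hbb-bt, Btf3l4b and Btf3l4, and the Lce1, Sprr2, Defb and Gstm families. With the strand setting not given, reads of overlapping or antisense genes may also be shared.

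Total counts per sample ran from 21226436 to 34333949. In a single sample 3 counts corresponded to 0.0813 to 0.143 CPM (the count of a gene scaled by the size of its library), taken as the floor of detection. The floors and the counting interval of Cd207 cover counting error only, and reads were not marked by molecule. All other intervals also reflect the spread between samples, but that of the Cd207 fold change is narrower than its counting interval and understates the uncertainty. No pair of samples in a group was a repeat of the same library: chi-square per degree of freedom between replicates was 6.25 to 55.6, far above sampling noise. The samples were taken to be separate mice, which the labels do not state for each one; otherwise p-values would measure only the spread between samples.

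Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr (minimum count 10), which left 14231 genes. Libraries were scaled by TMM, a trimmed mean that sets the compared genes to a common level, and CPM values were computed on the TMM-scaled libraries. The quasi-likelihood F test (two-sided) compared DT with PBS with no covariate, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Unless another test is named, each adjusted p of a gene is from this edgeR test. Standard errors (SE) were obtained from the fold change and its F statistic, and intervals are 95%. Values given as mean ± SD are over 6 samples.

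The gene lists, 32 in all, covered immune cells, nerves, epithelium, responses and other tissues that the preparation could hold. They were written before the data were examined, as were the main tests and most alternative settings. The 27 lists with at least 3 tested members were tested by camera in limma 3.58.1 on voom log2 CPM with a preset correlation between genes of 0.01, adjusted over these lists. The test was repeated with a correlation estimated from the data, and with fry. Camera compares a list with the other genes; fry asks whether a list's genes moved on balance and does not compare them with other genes. Members past the threshold were counted over all genes tested and adjusted over the list alone. List scores are the mean log2 CPM of the tested members, compared by a two-sided exact permutation test over the 6 and 6 samples, with 0.00216 as the smallest possible p.

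The genes to be named were also set beforehand. They were Cd207; the 10 largest rises and the 10 largest falls among genes past the threshold with a mean of at least 1 CPM and an established symbol; up to 4 members with the smallest p in each called list, and 2 to 4 in other lists described; and, in any case, a fixed set with Bdnf, Calca, Tac1, Cd74, H2-Ab1, Krt14, Krt13 and Krt4. Some genes that this rule names are not reported here. Genes named outside that rule, chosen after their values were seen, are said to be so where they appear.

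The test was tried on simulated counts for DT against PBS, drawn from the means and library sizes of these samples, with known changes set in some of the genes. Of the changed genes among 14061 tested, 70.1% were recovered at a log2 change of 0.5, 92.1% at 1 and 100% at 2. The simulation gave 184 calls, of which 14 were false (7.61%). The list test called the raised list and 0 of the unchanged lists. Genes were drawn independently of each other there, while the correlation estimated in the real samples was up to 0.845 within a called list. The simulation therefore could not show false list calls that come from such correlation.

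The settings tried were 3 other scalings, no filter and a stricter filter, the replicate number as a block, each sample left out in turn, the first surrogate variable (sva 3.50.0) as a covariate, DESeq2 1.42.0, limma-voom with quality weights, other thresholds, and the other list tests. A sex covariate was planned only if both sexes were present. Alternatives chosen after seeing the data were leaving out PBS 2 and PBS 5 together, the side of the first principal component as a covariate, the samples of each side alone, and the Langerhans cell list without Cd207. The labels give no batch, cage or hour of collection, and the library numbers follow the groups, so processing order and treatment cannot be told apart. A group of mice given the toxin without its receptor was not analysed here.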

Results

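Gene expression was measured in the tongue epithelium of Langerin-DTR mice that had received diphtheria toxin (DT, n = 6) or saline (PBS, n = 6) from early life to adulthood. The comparison asks how the epithelium differs when langerin-expressing cells, which in this tissue are Langerhans cells, are removed over that period, with the nerves of the oral mucosa as the stated interest of the study. Total counts per sample were 26542921 ± 3542030 in PBS and 30168530 ± 3059416 in DT (exact permutation p = 0.0909), and 14231 genes were tested. Krt4 and Krt13, keratins of differentiated oral epithelium, took 4.84% and 6.19% of all counts in PBS and 4.70% and 5.82% in DT (exact permutation p = 0.314 and p = 0.0952). Mitochondrial genes took 3.38 ± 0.845% of counts in PBS and 2.82 ± 0.292% in DT (exact permutation p = 0.149). The TMM scaling factor was 0.965 ± 0.0357 in PBS and 1.04 ± 0.0505 in DT (exact permutation p = 0.0238).

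Cd207 (ENSMUSG00000034783), which encodes langerin, was nearly lost in DT. Its counts were 53 to 92 in each PBS sample, 429 in all, against 4 over the 6 DT samples, of which 3 had 0 counts. The mean level was 2.80 ± 0.436 CPM in PBS and 0.0189 ± 0.0231 CPM in DT, and each DT value lay under the floor of 3 counts. The log2 fold change was -6.78 ± 0.32 (SE; 95% interval -7.46 to -6.10; edgeR adjusted p = 6.71e-09). This SE and interval come from the F statistic and are too narrow for a group with 4 counts. The counting interval that follows is wider. By the counts alone 0.759% of the PBS level was left (95% counting interval 0.206 to 1.96%), a ratio of 132 (51.1 to 486). Cd207 thus went with the group labels in 12 of 12 samples.

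**Figure D1:**
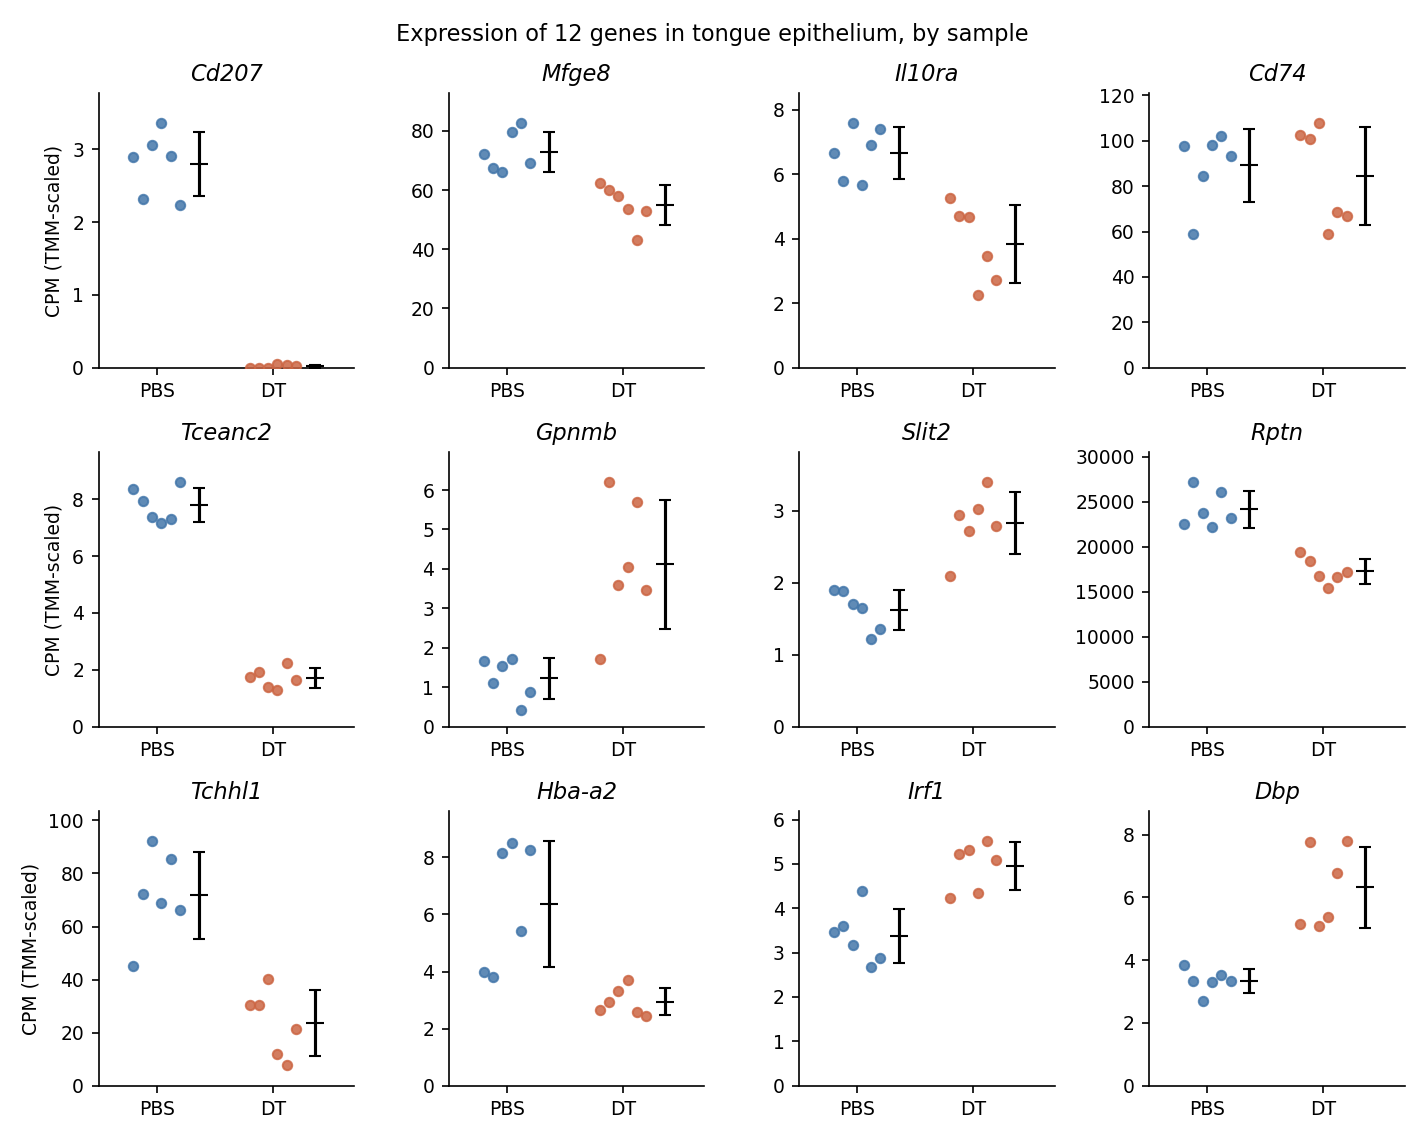
Expression of 12 genes in each sample, in TMM-scaled CPM on an axis from 0, with blue points for the 6 PBS samples, orange points for the 6 DT samples, and black marks for the mean ± SD. Cd207 lay at 2.24 to 3.36 CPM in PBS and at 0 to 0.0565 CPM in DT, while Cd74 overlapped between the groups.

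Among Langerhans cell markers, Cd207, Mfge8 and Il10ra fell and 11 of the 14 tested markers did not pass the test by edgeR, while 4 markers passed by DESeq2. Fold changes were negative for 9 of the 14 and positive for 5. Mfge8, a secreted protein that binds dying cells, went from 72.8 ± 6.77 to 55.0 ± 6.87 CPM (log2 fold change -0.41, adjusted p = 0.0291). Il10ra, a chain of the interleukin-10 receptor, went from 6.68 ± 0.808 to 3.85 ± 1.21 CPM (-0.81, adjusted p = 0.0348). Cd24a stood at -0.22 (787 ± 18.2 and 677 ± 29.8 CPM, adjusted p = 0.0511). Mfge8 and Cd24a were far more abundant than Cd207, and their relative falls were much smaller. Whether those falls came from the lost cells was not tested. Adjusted over the list alone, 5 markers were lower, and the list as a whole was lower by camera (median -0.13, mean -0.58, adjusted p = 0.000724; adjusted p = 0.402 with an estimated correlation). Without Cd207 the remaining 13 markers had a median of -0.06 and an adjusted p of 0.0269. The call of Mfge8 was lost in 8 of the 12 fits that each left out 1 sample (adjusted p up to 0.0650) and that of Il10ra in 9 (up to 0.0925), with DT 3, DT 4, DT 5, DT 6, PBS 1, PBS 2 and PBS 5 common to both.

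Genes of MHC class II antigen presentation, which Langerhans cells express strongly, did not pass the test for a difference. Cd74, the invariant chain, was at 89.1 ± 15.9 CPM in PBS and 84.3 ± 21.6 CPM in DT (log2 fold change -0.08, 95% interval -0.42 to 0.25, adjusted p = 0.860). H2-Ab1 was at 46.3 ± 7.78 and 42.3 ± 8.41 CPM (-0.13, -0.41 to 0.15, adjusted p = 0.692). By edgeR 0 of the 9 tested members passed, with 1 at an unadjusted p under 0.05 and 0 past the threshold by DESeq2. The list did not pass camera (median 0.02, adjusted p = 0.608), and H2-DMb2 (0.44, adjusted p = 0.274) and Ciita (0.24, adjusted p = 0.470) had the smallest p. Other dendritic cell markers (6 tested, with Irf8 at -0.27 and Flt3 at 0.25) and macrophage and monocyte markers (9 tested) also did not pass camera as lists (adjusted p = 0.608 for both). In the latter list 1 member passed by edgeR, lower in DT, and 1 by DESeq2. Cd68 in that list stood at -0.26 (adjusted p = 0.203), and the list had a median of -0.03 and a mean of 0.03. It passed fry for change in either direction (adjusted p = 0.00608).

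Across all genes, 185 passed the threshold, 63 higher and 122 lower in DT, with a median absolute log2 fold change of 0.43. The groups did not overlap for 138 of these genes; over all tested genes 314 had no overlap, against 30.8 for a chance share of 0.216%. After Cd207, the largest fall among called genes was in Tceanc2 (ENSMUSG00000028619), a relative of the transcription elongation factor TFIIS, which went from 7.79 ± 0.605 to 1.71 ± 0.346 CPM (-2.18 ± 0.12 SE, adjusted p = 3.46e-08). Cyp1a1 (-1.96, adjusted p = 0.0255) and Cyp1b1 (-1.56, adjusted p = 0.0223), enzymes induced through the aryl hydrocarbon receptor, fell as well. So did Tchhl1, a trichohyalin-like gene of cornifying epithelium (71.8 ± 16.4 to 23.6 ± 12.3 CPM, -1.61, adjusted p = 0.0189), and Pdk4, a kinase that restrains glucose oxidation (23.2 ± 7.18 to 10.2 ± 3.62 CPM, -1.19, adjusted p = 0.0223). Among called genes with a mean of at least 1 CPM and an established symbol, the others of the 10 largest falls were in Tcf23, Hba-a2, Cryba2 and Hba-a1, at -1.20 to -1.03. In all, 14 called genes had a log2 fold change of -1 or less, with less abundant genes among them such as Chga (-1.72, adjusted p = 0.00909; chosen after its values were seen).

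Under the same limits of abundance and symbol, the largest rises were in Sult5a1, a sulfotransferase (1.82 ± 0.38 SE, adjusted p = 0.0314), and Gpnmb, a glycoprotein of macrophages and pigment cells (1.22 ± 0.515 to 4.12 ± 1.64 CPM, 1.76 ± 0.31 SE, adjusted p = 0.0164). Tfcp2l1, a transcription factor of the grainyhead family, rose from 19.4 ± 4.16 to 36.7 ± 7.23 CPM (0.92, adjusted p = 0.0122). Slit2, a secreted axon guidance protein, rose from 1.62 ± 0.277 to 2.83 ± 0.431 CPM (0.82, adjusted p = 0.0164). Dbp, a transcription factor driven by the circadian clock, rose from 3.33 ± 0.381 to 6.32 ± 1.28 CPM (0.93, adjusted p = 0.00622). Camkv (1.04), Oasl1 (0.99), the retinoic acid receptor gene Rarb (0.88) and the matrix gene Prelp (0.88) rose too, with adjusted p of 0.0251 to 0.0341. Btf3l4b rose by 1.02 (adjusted p = 0.00954), but it is a near copy of Btf3l4 (-0.14, adjusted p = 0.375; chosen after its values were seen), so its counts are uncertain.

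**Figure D2:**
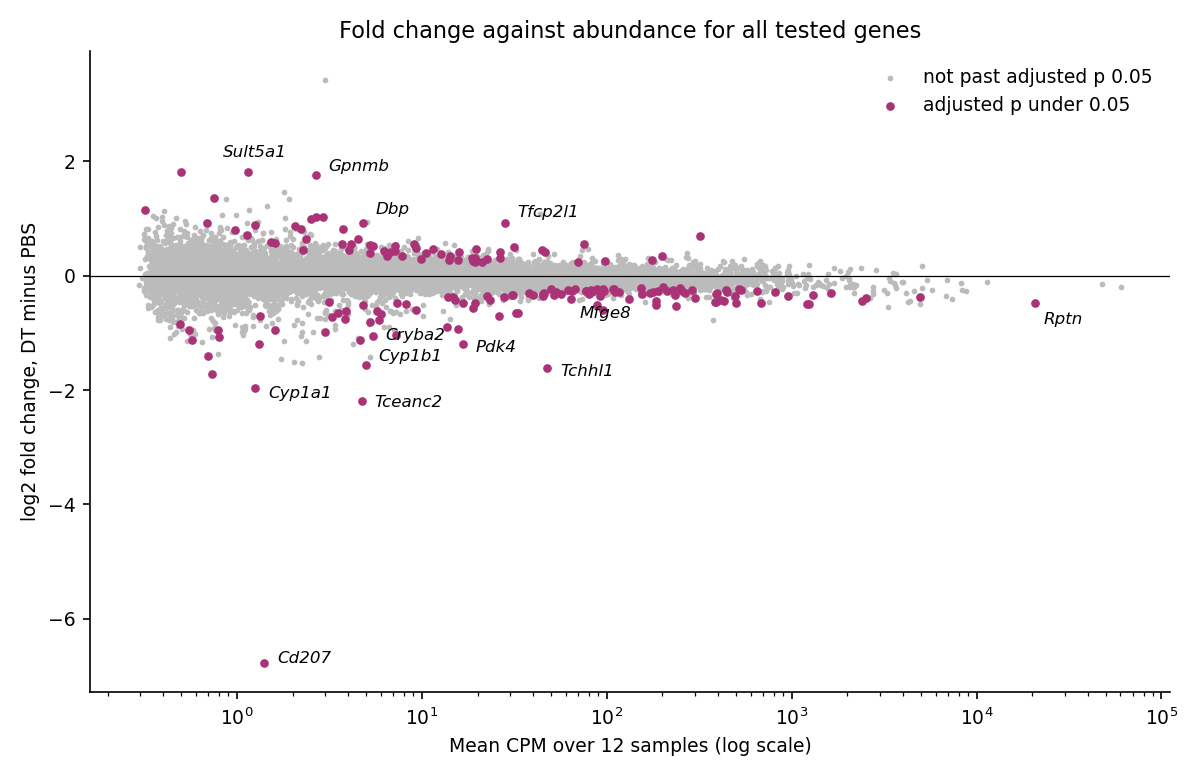
Log2 fold change, DT minus PBS, against mean CPM over the 12 samples (log scale) for the 14231 tested genes, with purple points for the 185 past an adjusted p of 0.05. Cd207 at -6.78 and Tceanc2 at -2.18 lie below the rest of the called genes of their abundance.

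Of the 20 genes with the largest changes within these limits, 9 kept their calls in each of the 12 fits that left out 1 sample: Cd207, Tceanc2, Tchhl1, Cryba2, Gpnmb, Btf3l4b, Dbp, Tfcp2l1 and Slit2. Hba-a2 was lost without DT 5 (adjusted p = 0.0508), Cyp1b1 without DT 3, DT 5 or PBS 2 (up to 0.0652) and Pdk4 without DT 5, PBS 2 or PBS 3 (up to 0.0644). Camkv was lost in 5 of these fits, Rarb and Cyp1a1 in 6, Oasl1 and Tcf23 in 7, Sult5a1 and Hba-a1 in 8 and Prelp in 11, with adjusted p of up to 0.10. The count of 185 fell to 97, 56, 67 and 115 without PBS 1, PBS 2, PBS 3 and PBS 4, to 102, 72, 77, 46 and 114 without DT 2, DT 3, DT 4, DT 5 and DT 6, and to 16 without PBS 2 and PBS 5 together. Higher genes made up 34.1% of the calls, 47.9% with upper quartile scaling and 87.5% with library size alone, which gave 553 calls and moved the median of all genes by 0.11.

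The samples also differed along an axis that the groups did not explain. The first principal component (26.6% of variance) set PBS 5, PBS 6, DT 1, DT 2 and DT 3 apart from the other samples, and the second (17.4%) separated DT from PBS. DT against PBS within the first set of 5 samples gave 3 calls, and within the other 7 samples 1120. Of the 9 lists called by camera below, 5 lost their call within the first set and 3 within the other. Scores of some of them followed the first component: cell cycle (correlation -0.789), inflammatory cytokines (0.700), differentiated tongue keratinocytes (0.639) and cornified envelope (0.599). Others did so less, such as fibroblasts (0.103) and erythrocytes (0.213).

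**Figure D3:**
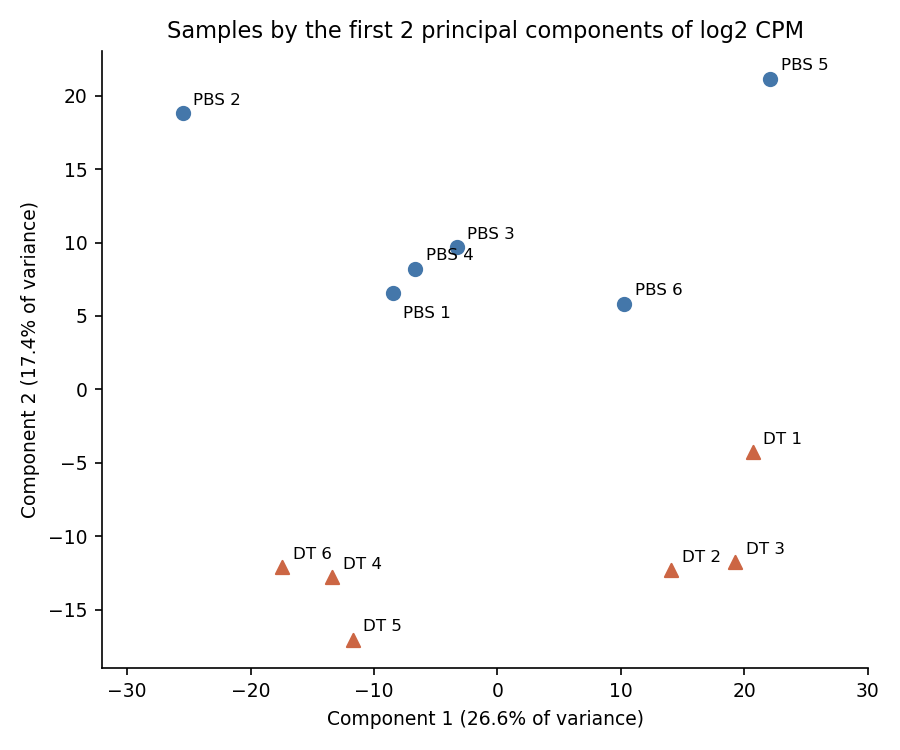
The 12 samples by the first 2 principal components of log2 CPM, with circles for PBS and triangles for DT. The first component (26.6% of variance) splits both groups, and the second (17.4%) has all PBS samples above 0 and all DT samples below 0.

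Genes of the outermost epithelial layers had mostly negative fold changes in DT. Both lists of them passed camera but neither fry for a shift on balance nor the permutation test of list scores. By fry for change in either direction the cornified envelope list passed (adjusted p = 0.00797) and that of differentiated tongue keratinocytes did not (adjusted p = 0.102). In the cornified envelope list, proteins cross-linked under the surface of cornifying cells, 15 of 21 tested members had negative fold changes (median -0.19). Rptn, an abundant envelope protein of the tongue, fell from 24149 ± 2037 to 17264 ± 1415 CPM (-0.48, adjusted p = 0.0164), and Sprr1b fell from 450 ± 57.2 to 328 ± 37.1 CPM (-0.46, adjusted p = 0.0249; lost in 5 fits that left out 1 sample, without DT 2, DT 4, DT 5, PBS 2 or PBS 4, up to 0.0674). Hrnr (-0.44, adjusted p = 0.0511) and Sprr2h (-0.42, adjusted p = 0.107) came next, and 8 members were lower when adjusted over the list alone. The list passed camera (adjusted p = 3.44e-05; adjusted p = 0.402 with an estimated correlation) but not fry for a shift on balance (adjusted p = 0.116), and its score differed by -0.142 on the log2 scale (exact permutation p = 0.279, adjusted p = 0.471). Of 15 markers of differentiated tongue keratinocytes, 13 were negative, and Krt78, a keratin of that layer, was the member that passed by edgeR, both over all genes and over the list alone (-0.37, adjusted p = 0.0441; lost in 10 of the 12 fits, up to 0.116), against 2 members by DESeq2. That list was lower by camera (adjusted p = 0.000495, and 0.402 with an estimated correlation) but did not pass fry for a shift on balance (adjusted p = 0.131). Its score differed by -0.198 (exact permutation p = 0.0779, adjusted p = 0.234). Krt13 (-0.19, adjusted p = 0.371), Krt4 (-0.14, adjusted p = 0.452) and the basal keratin Krt14 (-0.11, adjusted p = 0.515) did not pass.

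The basal keratinocyte list did not pass camera (13 tested, median 0.01, adjusted p = 0.446); Itgb4 stood at 0.18 and Igfbp2 at -0.15. Cell cycle genes were lower as a list (18 of 20 negative, median -0.13, adjusted p = 0.0195; adjusted p = 0.558 with an estimated correlation). By edgeR 0 of its members passed, with 1 at an unadjusted p under 0.05 and 0 by DESeq2; Mcm5 (-0.21, adjusted p = 0.300) and Rrm2 (-0.22, adjusted p = 0.342) had the smallest p. The list's call was lost without PBS 2 (adjusted p = 0.237), DT 1 (0.0866), DT 2 (0.182) or DT 3 (0.113). Its scores in DT 1, DT 2 and DT 3 (4.34, 4.28 and 4.31) lay below the PBS range of 4.40 to 4.84. Those in DT 4, DT 5 and DT 6 (4.66, 4.58 and 4.51) lay within it. Apoptosis and p53 target genes did not pass (14 tested, adjusted p = 0.608), with Bax at 0.19 and Bbc3 at 0.20.

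Among defence genes of the epithelium, the beta-defensin Defb3 fell from 32.4 ± 5.10 to 19.9 ± 4.33 CPM (-0.70, adjusted p = 0.0199; 0.0507 at most, without DT 3 or PBS 2). The antimicrobial list, with 14 tested members, was lower by camera (median -0.15, adjusted p = 0.0195; adjusted p = 0.413 with an estimated correlation), although its mean was 0.09. That mean rests on lactoferrin, Ltf, at 0.493 ± 0.173 CPM in PBS and 5.48 ± 7.18 CPM in DT (3.42, adjusted p = 0.0620). DT 2 and DT 3 stood at 11.1 and 17.6 CPM and the other DT samples at 0.533 to 1.46 CPM. Leaving out 1 sample gave Ltf a log2 fold change of 2.60 to 3.67, and it passed without DT 1 (adjusted p = 0.0290). The list's call was lost without PBS 5 (0.0584), DT 4 (0.128) or DT 6 (0.0768). Inflammatory cytokines (10 tested, median -0.12) were also lower by camera (adjusted p = 0.0377; adjusted p = 0.426 with an estimated correlation). Among them Areg, an EGF receptor ligand, fell from 7.40 ± 0.875 to 4.69 ± 0.937 CPM (-0.66, adjusted p = 0.0216; 0.0508 without DT 4), and Il1a stood at -0.29 (adjusted p = 0.225). The cytokine list's call was lost without PBS 4 (0.0522), PBS 5 (0.0584), PBS 6 (0.0761), DT 4 (0.128), DT 5 (0.128) or DT 6 (0.163). Its scores in DT 1, DT 2 and DT 3 (3.33, 3.28 and 3.37) lay within the PBS range of 3.06 to 3.42. Those in DT 4, DT 5 and DT 6 (2.91, 2.82 and 2.93) lay below it. The IL-17 response list did not pass (6 tested, adjusted p = 0.169; 0.0251 without DT 1); Il36b stood at -0.30 and Il36g at -0.22.

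Interferon-gamma response genes were the list that was higher. All 10 tested members had positive fold changes (median 0.18), and Irf1, a transcription factor induced by interferons, rose from 3.36 ± 0.610 to 4.96 ± 0.532 CPM (0.56, adjusted p = 0.0355). Gbp2, an interferon-induced GTPase, rose from 0.860 ± 0.161 to 1.42 ± 0.221 CPM (0.71, adjusted p = 0.0488), and Tap1 stood at 0.21 (adjusted p = 0.177). The list passed camera (adjusted p = 0.0101; adjusted p = 0.354 with an estimated correlation), with 3 members higher when adjusted over the list alone. The calls of Irf1 and Gbp2 were lost in 10 and 11 of the 12 fits that left out 1 sample (adjusted p up to 0.0984 and 0.111). The type I interferon list did not pass (16 tested, adjusted p = 0.608), and Oasl1 was its called member, next to Usp18 at 0.80 (adjusted p = 0.308). Markers of alpha-beta T cells (4 tested, adjusted p = 0.326; Cd3e at 0.52) and of natural killer and innate lymphoid cells (3 tested, adjusted p = 0.379; Il18r1 at 0.36 and Klrd1 at 0.38) did not pass either. Gamma-delta T cells, B and plasma cells, neutrophils, mast cells and minor salivary glands had 1 or 2 tested members each and were not tested as lists.

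**Figure D4:**
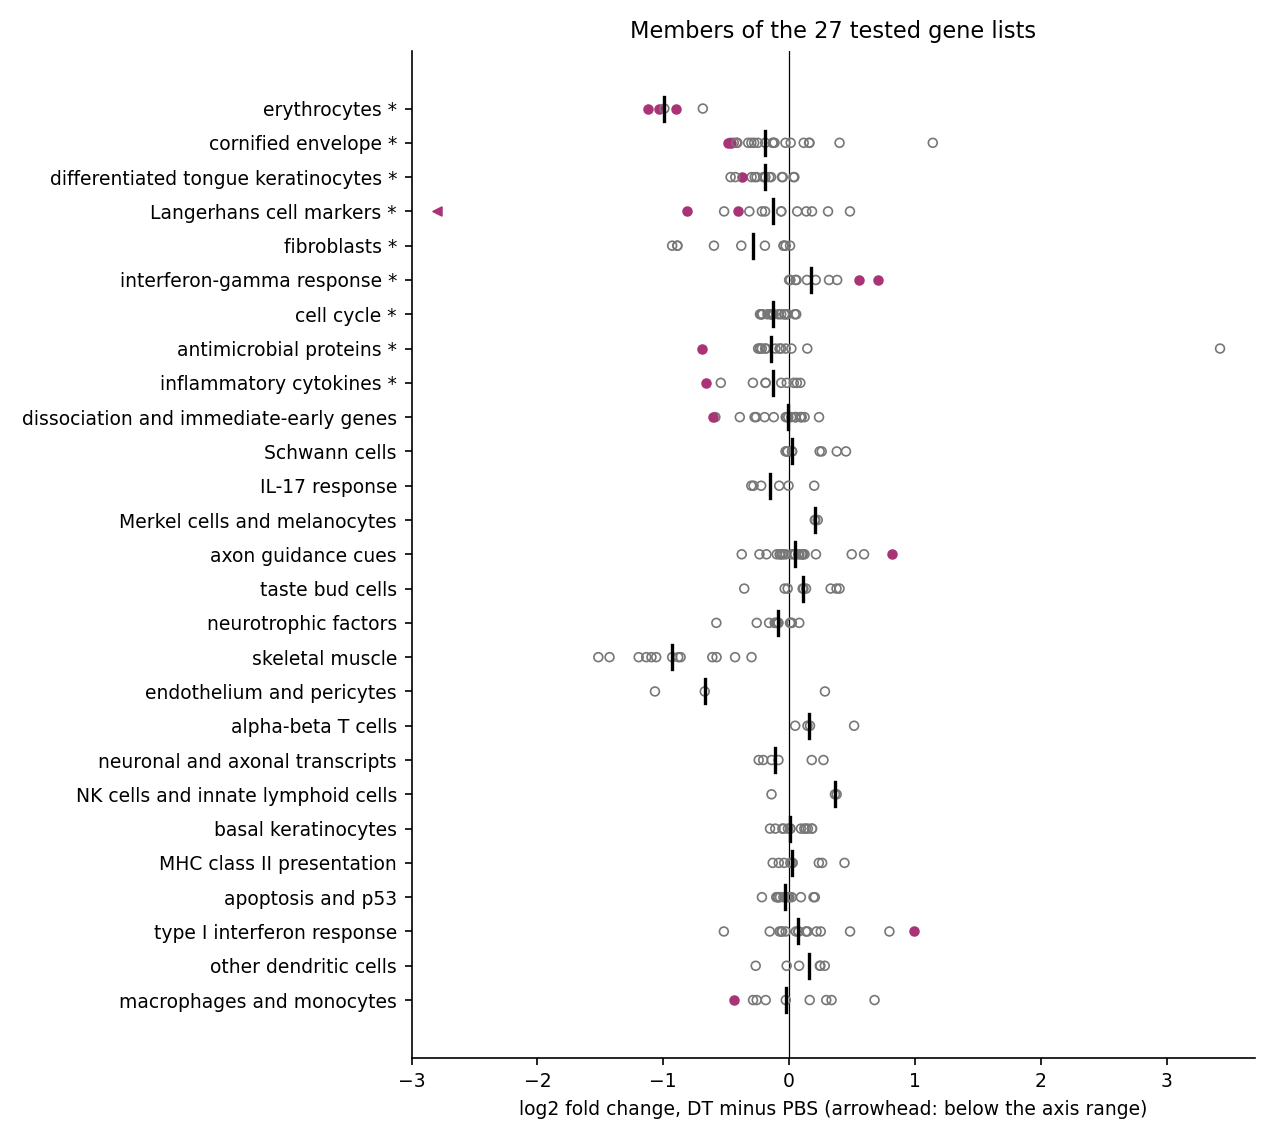
Log2 fold changes, DT minus PBS, of the tested members of 27 gene lists (open circles; filled purple past an adjusted p of 0.05), with a black bar at each list's median and an asterisk at the 9 lists past camera's threshold. Cd207, at -6.78, is drawn as an arrowhead at the left edge.

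Single transcripts of nerves and of factors that act on them rarely passed, and their lists gave results that differed between the tests. Of 26 neuronal and axonal transcripts only 6 were abundant enough to test, and 0 of them passed by edgeR or DESeq2, with 1 at an unadjusted p under 0.05. Tubb3, which keratinocytes can also express, stood at -0.24 (adjusted p = 0.250) and Ret at -0.21 (adjusted p = 0.650), and the list did not pass camera (adjusted p = 0.379). Calca, which encodes the sensory neuropeptide CGRP, had 0 counts in PBS and 2 in DT over 6 samples each. Tac1, which encodes substance P, had 5 and 10. These counts are too few to detect a difference, and they do not show whether the nerves differed. Whether depth or a low share of nerve RNA in the epithelium kept them low was not tested. Bdnf, a neurotrophin, did not pass (0.01, 95% interval -0.24 to 0.26, adjusted p = 0.986). The neurotrophic factor list (12 tested, median -0.09) did not pass camera (adjusted p = 0.226). Its members moved down on balance by fry (adjusted p = 0.0235), with Mdk at -0.58 and Vegfa at -0.16. Its score differed by -0.104 on the log2 scale (exact permutation p = 0.00649, adjusted p = 0.0584). The Schwann cell list (9 tested, median 0.02) did not pass camera (adjusted p = 0.156) and moved up on balance by fry (adjusted p = 0.0152). In it, Ngfr stood at 0.26 (adjusted p = 0.149) and Mal at 0.45 (adjusted p = 0.268). The Schwann cell score differed by 0.158 (exact permutation p = 0.00649, adjusted p = 0.0584). Whether Schwann cells were the source of these transcripts was not tested.

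Among 23 axon guidance cues, Slit2 was the member that passed by edgeR, and 2 members passed by DESeq2; Ntn4 (0.60, adjusted p = 0.0673) and Sema3d (0.50, adjusted p = 0.133) had the next smallest p, and 3 members were higher when adjusted over the list alone. The list passed neither camera (adjusted p = 0.226) nor fry for a shift on balance (adjusted p = 0.131). It passed fry for change in either direction (adjusted p = 0.0313). Taste bud cell markers (9 tested, adjusted p = 0.226), with the ATP-degrading enzyme Entpd2 at 0.38 (adjusted p = 0.125) and Krt18 at 0.40 (adjusted p = 0.321), and Merkel cell and melanocyte markers (3 tested, adjusted p = 0.224), with Piezo2 at 0.20 and Dct at 0.23, also did not pass.

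Markers of blood, connective tissue and muscle also had mostly negative fold changes, beside the epithelial changes above. Haemoglobin genes fell: 3 of 5 tested erythrocyte genes passed over all genes and 5 over the list alone, with Hba-a2 at 6.37 ± 2.21 and 2.95 ± 0.486 CPM (-1.12, adjusted p = 0.0172) and Hbb-bs at -0.90 (adjusted p = 0.0472; lost in 10 of the 12 fits, up to 0.119). The list was lower by camera (median -0.99, adjusted p = 1.07e-05; adjusted p = 0.354 with an estimated correlation). Fibroblast genes were lower as a list (9 of 10 negative, median -0.29, adjusted p = 0.00981; adjusted p = 0.354 with an estimated correlation), with 4 members lower when adjusted over the list alone. Over all genes 0 of them passed by edgeR, with 4 at an unadjusted p under 0.05 and 1 past the threshold by DESeq2; Col6a1 stood at -0.89 (adjusted p = 0.0802) and Col3a1 at -0.89 (adjusted p = 0.122). All 13 tested skeletal muscle genes were negative (median -0.93) with large spread, as for Myh1 at 3.05 ± 3.07 and 1.01 ± 0.932 CPM; the list did not pass (adjusted p = 0.244; 0.00240 without PBS 5). Endothelial markers did not pass (3 tested, adjusted p = 0.256), with Tie1 at -1.07 (adjusted p = 0.0553) and Pecam1 at -0.67 (adjusted p = 0.203). Genes induced by tissue dissociation did not pass (19 tested, adjusted p = 0.121; 0.0220, 0.0219, 0.0460 and 0.0310 without DT 1, DT 4, PBS 1 and PBS 2), but Fosl1, an AP-1 subunit, fell from 11.2 ± 1.31 to 7.37 ± 1.21 CPM (-0.60, adjusted p = 0.0164).

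Camera thus called 9 of 27 lists, 1 higher and 8 lower, against 0 with an estimated correlation, 6 by fry for a shift on balance and 8 by fry for change in either direction. Of these 9 lists, those of Langerhans cells, fibroblasts, erythrocytes and the interferon-gamma response passed fry for a shift on balance. By exact permutation of the list scores 0 of 27 lists passed after adjustment (lowest adjusted p = 0.0584), with 8 at an unadjusted p under 0.05. Of 100 splits of the 12 samples into 6 and 6, the real one included, 22 gave at least 9 lists.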

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

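The alternative without PBS 2 and PBS 5 was chosen after these values were seen; the other checks of this part followed a rule set in advance. In 310 checks of the highest and lowest sample of a group, 11 values stood apart from the other 5 samples by more than the limit used; about 15.5 would do so by chance, so the number of such values is not in itself unusual.

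In PBS 5, 4 values stood apart. Krt6b, a keratin of stressed epithelium and of filiform papillae, was at 8298 CPM against 3812 to 5303 CPM in the other PBS samples, and Krt13 was at 76085 CPM against 58718 to 63807 CPM. Areg was at 9.13 CPM against 6.74 to 7.37 CPM, and the TMM factor was 0.894 against 0.975 to 0.992. In PBS 2 there were also 4. Piezo2 was at 9.03 CPM against 6.12 to 6.80 CPM, Usp18 at 1.10 CPM against 0.229 to 0.523 CPM, and Per3 was lowest at 8.07 CPM against 9.17 to 9.46 CPM. The basal keratinocyte list in PBS 2 had a mean log2 CPM of 8.48 against 8.28 to 8.35. The others were Mylpf in DT 6 (4.82 CPM against 2.56 to 3.22 CPM), Tie1 in DT 1 (0.640 CPM against 0.387 to 0.481 CPM) and the Krt4 share of PBS 1 (5.08% against 4.73 to 4.85%).

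Without PBS 2 and PBS 5 together, 16 genes passed the threshold, 6 higher and 10 lower, of which 15 were among the 185 called with all samples.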

How the results depend on the processing

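The alternatives without PBS 2 and PBS 5, with or within the sides of the first component, and without Cd207 in its list were chosen after the data were seen. Cd207 kept its direction and its call in each fit that gave it a value (-9.15 to -6.12); the stricter filter removed it. No gene called in the report changed direction in any alternative, while 37 of 3689 comparisons of a gene or list, past the threshold in neither fit, changed sign, among them Bdnf. The gene count of 185 (63 higher, 122 lower) was 178 with DESeq2's size factors and 169 with upper quartile factors. It was 553 (484 and 69) by library size alone, which leaves the TMM difference between groups in the values and called 14 lists; 224 with no filter and 135 with the stricter one; 576 (189 and 387) with DESeq2, 331 (128 and 203) with limma-voom and quality weights; 21 (7 and 14) with an absolute log2 fold change of at least 1, and 455 (190 and 265) at an adjusted p of 0.1. With the first surrogate variable 1295 genes passed (470 and 825), with the side of the first component 1017 (346 and 671), and each fit held the 185. Within the 7 samples on the negative side 1120 passed (398 and 722), within the 5 on the positive side 3 (0 and 3, with 2101 at an unadjusted p under 0.05). There the skeletal muscle list turned higher (adjusted p = 0.000322). The cause of these differences was not tested. Without PBS 2 and PBS 5, with fewer samples, the count was 16 (6 and 10). Leaving out 1 sample gave 46 to 263 genes, 16 to 104 higher and 30 to 159 lower, and 7 to 10 lists. The count of 9 lists fell to 0 with an estimated correlation, which was up to 0.845 within a called list. Shared replicate numbers did not pair the samples: same-number correlations were -0.325 to 0.107, with 1 of 6 over 0.1, and 0 of 6 PBS samples were closest to their own number. With the number as a block 8 genes passed (1 and 7) and 9 lists. A sex covariate was not run, since all samples had the male pattern. Low counts left 20 of 26 nerve transcripts untested. Low counts and missing count entries left 5 lists with 1 or 2 tested members. Only 4 of 12 gamma-delta T cell genes and 8 of 11 B and plasma cell genes had count entries.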

Other observations

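The tests of the epidermal differentiation complex, of MHC class II transcripts, of the Tceanc2 level left and of the clock genes were chosen after the values were seen. So were the genes named in the next 2 paragraphs. The tests on splits of the samples were set before. Those on the neighbours and overlaps of Tceanc2 were written before their own outcomes were seen, but after the fall of Tceanc2 was.

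Called falls were concentrated in the epidermal differentiation complex, the gene cluster that encodes most cornified envelope proteins. From Lor to Tchhl1 in the order of the reference annotation, 47 genes were tested, of which 9 were lower, 0 higher, and 36 had negative fold changes (median -0.33). Called falls made up 19.1% of the tested genes there and 0.797% elsewhere (Fisher's exact p = 1.92e-10). The cluster was chosen after its falls were seen, and neighbouring genes are not independent. This p therefore describes the called falls and does not test them. Beside Rptn, Sprr1b and Tchhl1, they included the late envelope genes Lce1d (-0.48), Lce1e (-0.52), Lce1f (-0.43) and Lce1g (-0.43) and the keratinocyte protein gene Kprp (-0.44). Reads of the Lce1 genes can be shared among the copies. The call of Lce1e held in each fit that left out 1 sample, and that of Lce1d was lost without DT 5 or PBS 2 (up to 0.0564). The call of Lce1f was lost in 8 of the 12 fits (up to 0.0925), that of Lce1g, with an adjusted p of 0.0497, in 11 (up to 0.120) and that of Kprp in 10 (up to 0.113).

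Other single genes also passed, and no test of a group stands behind them. The cytochrome P450 gene Cyp2f2 rose from 244 ± 50.4 to 397 ± 74.6 CPM (0.70, adjusted p = 0.0251) and the carbonyl reductase Cbr2 from 26 ± 2.36 to 36.8 ± 2.98 CPM (0.50, adjusted p = 0.00622). The glutathione transferases Gstm1 (0.35), Gstm4 (0.42) and Mgst1 (0.31) and the monooxygenase Fmo5 (0.64) had adjusted p of 0.0373 to 0.0461. Cyp26b1, which degrades retinoic acid, fell from 40.3 ± 3.65 to 25.6 ± 4.84 CPM (-0.66, adjusted p = 0.0122). Chga, a protein of neuroendocrine granules, fell from 1.13 ± 0.304 to 0.348 ± 0.141 CPM (-1.72, adjusted p = 0.00909). The calls of Cbr2, Cyp26b1 and Chga held in each fit that left out 1 sample; those of Cyp2f2, Gstm1, Gstm4, Mgst1 and Fmo5 were lost in 5 to 11 of them (up to 0.117).

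The gene count stood out among the splits of the samples that were drawn, and the list count did not. Of 100 splits of the 12 samples into 6 and 6, only 1, the real one, gave as many as 185 genes, and the highest other count was 2. For lists, 22 of the 100 splits gave at least 9, and the highest other count was 12. Each other split mixed DT and PBS samples, so the difference between the groups added to its spread and could lower its gene count. The splits therefore cannot exclude an unlabelled difference between the groups, such as processing order.

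MHC class II transcripts did not pass the test for a difference although Cd207 was nearly lost. A small fall hidden by the main axis of variation stays open. With the first surrogate variable in the model, the difference of the MHC class II score was 0.0473 on the log2 scale (95% interval -0.174 to 0.268), against 0.0841 without it. For these 9 genes as a set, that interval argues against a fall near the size of that of Cd207 (-6.78). A rise of other antigen-presenting cells that might offset the loss also stays open, since the joint score of 15 dendritic cell and macrophage genes differed by 0.0880 (-0.205 to 0.381). With the surrogate variable in the model that score differed by 0.0598 (-0.119 to 0.239). The intervals are too wide to decide between them. That Langerhans cells give only a small share of these transcripts in this preparation was not tested.

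Among called genes Tceanc2 had the largest fall after Cd207. Langerhans cells as its only source were argued against: 22.0% of its PBS level was left (95% interval 18.4 to 26.3%), against 0.759% for Cd207. A chromosomal stretch that differs between the mice of the groups may be a source and stays open, since 25% of its 20 nearest tested neighbours had an unadjusted p under 0.05, against 15.4% of all tested genes (one-sided Fisher's exact p = 0.183). Reads passed to an overlapping gene could not be tested, as 0 tested genes overlapped it in the reference. An effect of the toxin on its transcription was not tested.

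Of 16 tested clock genes, 11 of the daytime side and 5 of the opposite side, 15 had the sign of a shift towards the daytime side, and Dbp, Tef (0.44), Per3 (0.40), Ciart (0.64) and Clock (-0.28) passed. The signed score of these 16 genes differed by 0.545. With the first surrogate variable in the model it differed by 0.561 (95% interval 0.384 to 0.738). This cannot decide whether variation along that variable lay behind the shift. The variable spanned much the same range in PBS (-0.4461 to 0.3875) and DT (-0.3757 to 0.3686), so it could change the difference little. The score also included the genes that had passed for DT against PBS. A difference in clock phase at collection stays open. Over the 11 clock genes that did not pass singly the score differed by 0.375, but the signs of these genes had been seen before, so this value decides nothing. A different hour of dissection for the groups and an effect of the lost cells on the tissue clock were not tested; the labels give no hour. The calls of Ciart and Clock were lost in 8 and 11 of the 12 fits that left out 1 sample (adjusted p up to 0.0850 and 0.109).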
